A study of Homo sapiens with 60 samples.

How the data were processed

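RNA was measured by sequencing in A549 cells after 24 h with extract or vehicle. Per the labels' protocols, total RNA with an integrity number above 7 was made into directional messenger RNA libraries (MGIEasy RNA Directional Library Prep) and sequenced as 100 bp paired-end reads on an MGIseq instrument. Vehicle was labelled as 0.1% DMSO on the samples and as 2% in the series' design text, and which is right is not settled. The text on extract preparation ends before it says how extracts were dissolved. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 were used with the build GRCh38 (hg38). The annotation release and the strand setting of the counting are not given, so values of antisense and overlapping genes are uncertain. The deposited table held expected counts per gene as RSEM gives them, not normalized, and 9.37% of the values used were not whole. Ethanol extracts and the positive control that the design text mentions were not analysed here.

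The deposited file had 269 sample columns, of which 60 matched a sample of this series by its label and were used, and 209 belonged to other samples and were not used. Of 60675 gene identifiers, 57055 were found in GENCODE 29, which gave gene types, lengths and coordinates on GRCh38, and 56558 had a symbol. Coordinates are those of that release, which may not be the one the authors counted on.

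Expected counts were rounded to whole numbers. A single edgeR quasi-likelihood model (edgeR 4.0.16 in R 4.3.3) was fitted to 57 libraries in 19 groups of 3, with TMM scaling and the default low-count filter by group, which kept 17269 genes. It left 38 residual degrees of freedom, a common dispersion of 0.01026 (a biological coefficient of variation of 10.1%) and prior degrees of freedom of 4.69. P-values were adjusted by Benjamini-Hochberg within each comparison, and 0.05 was the threshold. The standard error of a log2 fold was its size over the square root of its F statistic. The 27 comparisons set each dose of 6 extracts against vehicle, high against low dose within an extract, and high doses of extracts sharing a set label against each other. In addition, all 15 pairs of low-dose groups were tested. Bojungikgi stayed outside the model with 1 library per dose. Its differences are of log2 CPM with a pseudocount of 1, without a test.

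Gene lists, 33 in number, were tested with limma's camera (limma 3.58.1) on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all lists of a comparison. An estimated correlation served as the alternative. Members were counted as risen or fallen by the gene test over all genes and again adjusted over the list alone. A further 7 lists were added after the data had been seen and are used only in the closing part.

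Named genes followed a rule. For high dose against vehicle these were the 8 largest rises and 8 largest falls among genes past the threshold with at least 5 CPM in the higher group and no overlap between the 3 and 3 libraries, a condition that chance meets for 10% of genes, and up to 4 members of each list past the threshold. For high against low and high against high dose the number was 5 in each direction and for medium and low doses against vehicle 3. For Bojungikgi the rule took 8 in each direction with a mean of at least 10 CPM. Clone and LINC names were passed over, and a panel of 12 genes (CYP1A1, CYP1B1, NQO1, HMOX1, TXNIP, DDIT3, CDKN1A, HMGCS1, MT2A, CXCL8, TOP2A and HSPA5) was followed in every extract. Groups, comparisons, tests, lists, this rule and the alternatives named in the next paragraph up to the estimated correlation were chosen before the data were examined.

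Libraries were checked for total counts, for shares of mitochondrial and ribosomal protein genes, for replicates alike within sampling noise (chi-square over genes with a count sum of at least 20) and for the balance of transcripts over 6 kb against those under 1.5 kb in mean log2 CPM. Genes at or near 1 CPM have few reads in a library, so their folds are less certain. Alternatives were RLE size factors, DESeq2 1.42.0 with its Wald test, no low-count filter, a fit of only the 6 samples compared, the replicate number as a block, leaving out each of 57 libraries in turn and, for lists, the estimated correlation. Chosen after seeing the data were a robust fit, the length balance as a covariate, mitochondrially encoded genes removed before scaling, and a shared fit without Citri medium replicate 1. The comparison of Yijung high with Yijung medium dose was also added then.

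The scripts were tested on simulated data for Citri high against vehicle. Over 17089 genes the shared fit found 76 of 100 genes changed 1.5-fold and 93 of 99 genes changed 2-fold, with 14 false calls. A fit of the 6 samples alone found 58 and 85 with 7 false calls over 15665 genes. DESeq2 on those 6 found 74 and 90 with 48 over 17262. The list test found the planted list of 24 and none of 32 others. Tables and plots were made with pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and, in R, version 1.17.8 of data.table. Results for some single genes are not reported here.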

Results

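RNA sequencing counts were analysed from 60 libraries of A549, an established human non-small-cell lung cancer line, kept for 24 h with a vehicle or with a hot-water extract used in Korean herbal medicine. A set of 6 extracts was given at a high, a medium and a low dose with 3 libraries at each dose, beside 3 vehicle libraries. The single herbs were Citri Unshius Pericarpium (tangerine peel), Cimicifugae Rhizoma, Bupleuri Radix and Aconiti Lateralis Radix Preparata (processed aconite root), and the herb mixtures were Yijung-tang and Banhasasim-tang. Doses were 500, 100 and 20 µg/mL, except for Aconiti with 360, 72 and 14.4 µg/mL, since an extract whose IC20 lay below 500 µg/mL was given at that concentration and dilutions of it. A further mixture, Bojungikgi-tang, had 1 library per dose. Extracts are called by the opening word of their names. The series set out to record what each extract does to the expressed genes of the line. The comparisons listed above were therefore made. Vehicle carries a set label of its own, so a difference between sets cannot be told apart from an effect of extract in any comparison with vehicle, whereas the high and low doses of 1 extract share a label. The labels give DMSO for vehicle alone and do not say whether extract samples held as much, so an effect of DMSO is not separated from that of extract in comparisons with vehicle. The labels do not say that replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

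Total counts ran from 17793680 (Yijung high replicate 3) to 30188212 (Yijung high replicate 2) with a median of 25758935, and 22170 to 24025 genes were detected in a library. No pair of replicates agreed within sampling noise, the closest (Banhasasim medium replicates 2 and 3) having a chi-square per degree of freedom of 2.03. Mitochondrially encoded genes took 8.297% ± 0.342 of counts in vehicle (SD, n = 3), 8.679% ± 0.887 in Aconiti low, 14.05% ± 0.984 in Aconiti medium and 17.47% ± 1.31 in Aconiti high. Citri medium replicate 1 stood apart. Its ribosomal protein genes held 8.994% of counts, the highest share of the 60 libraries, and its long transcripts (over 6 kb) exceeded short ones (under 1.5 kb) by only 2.483 on the log2 scale, the lowest such balance, against 3.361 to 3.523 in vehicle. The balance also lay below all 3 vehicle libraries in 23 of the 57 libraries outside Bojungikgi, the lowest after that one being Cimicifugae low 2 (2.866), Aconiti high 2 (2.978) and 3 (3.012), Bupleuri medium 1 (3.02), Aconiti low 3 (3.051), Cimicifugae medium 2 (3.061) and Yijung high 2 (3.086). The first principal component held 20.3% of the variance and the second 7.27%. Across 57 libraries the first followed the balance, itself computed from the same values and compared with it after the data were seen, with Pearson's r = -0.985 and Spearman's rho = -0.957 (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give), r = -0.974 without Citri medium 1 and Cimicifugae low 2, and r = -0.996, -0.986 and -0.963 within the 3 sets of 18 libraries, the vehicle set being too small. For the second component r was 0.014.

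Of 17269 genes tested, Aconiti changed the most against vehicle at the high dose, 5652, followed by Yijung with 1224. At the medium dose Yijung changed 1355 genes and Aconiti 399, and no other extract more than 6. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a threshold of 0.05. Levels are in CPM (counts scaled to a common library size), mean ± SD of 3 libraries, and changes are log2 folds ± standard error. Coordinates are on GRCh38. Counts depended on the samples fitted. On the 6 samples of a comparison alone, those for high dose against vehicle were 52 for Citri, 1932 for Cimicifugae, 1024 for Bupleuri, 4275 for Aconiti, 622 for Yijung and 144 for Banhasasim, and from low to high dose 33, 11, 41, 1501, 344 and 7 in the same order. With the length balance as a covariate they were 41, 1384, 645, 6591, 2705 and 179 against vehicle. The counts by dose are plotted for every extract, and the libraries on which each depends are given with that extract, apart from Aconiti medium, which fell from 399 to 208 without vehicle 1, 225 without vehicle 2, 250 without medium replicate 2 and 226 without medium replicate 3.

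**Figure D1:**
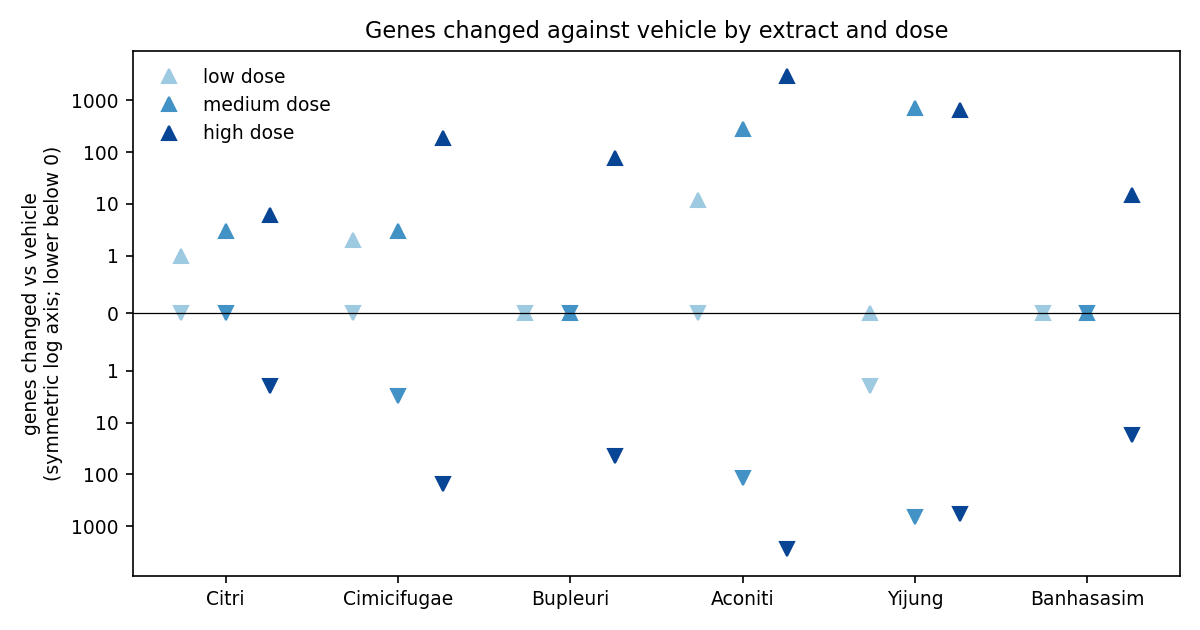
Number of genes changed against vehicle (vertical symmetric log axis, genes higher above 0 and lower below 0) for 6 extracts (horizontal axis) at the low, medium and high dose, 3 libraries per group, 1 count per point and no error bar. Aconiti rises from 12 genes at the low dose to 399 and 5652, whereas Yijung goes from 2 to 1355 at the medium dose and 1224 at the high dose.

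The cytochrome P450 gene CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902, protein-coding), a target of the aryl hydrocarbon receptor, rose with the high dose of Citri, from 53.9 ± 1.17 to 94.4 ± 6.99 CPM (0.81 ± 0.10, adjusted p = 1.46e-05). INSIG1 (ENSG00000186480, chromosome 7, 155297776 to 155310235), whose product holds back sterol synthesis and which is itself switched on when cells lack sterol, rose from 36.3 ± 2.31 to 46.6 ± 1.05 CPM (0.36 ± 0.05, adjusted p = 0.000255). CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610), another receptor target, rose by 1.12 ± 0.21 from a low level of 0.848 ± 0.297 CPM (adjusted p = 0.013). The nuclear receptor gene NR4A1 (ENSG00000123358, chromosome 12, 52022832 to 52059507) fell by 0.40 ± 0.07 (adjusted p = 0.013) and the fibrinogen chain gene FGA by 0.36 ± 0.07 (adjusted p = 0.0309). By fixed list, 3 of 9 aryl hydrocarbon receptor targets rose, but 1 without vehicle 1, vehicle 3 or any of the 3 high libraries, and 4 adjusted over the list alone (camera adjusted p = 3.21e-12), and of 24 cholesterol synthesis and uptake genes only INSIG1 rose, 4 adjusted over the list alone (2.46e-15). In all, 8 genes changed, 6 higher and 2 lower, and 631 had an unadjusted p under 0.05. Without vehicle 1, vehicle 3 or any of the 3 Citri high libraries the count was 2, and without vehicle 2 it was 5. The call for CYP1A1 ended without vehicle 1 (adjusted p = 0.104), vehicle 3 (0.168) or high replicate 1 (0.128), 2 (0.069) or 3 (0.0532), that for NR4A1 without vehicle 1 (0.089), vehicle 3 (0.115) or high replicate 1 (0.128), 2 (0.069) or 3 (0.0532), and that for FGA without vehicle 1 (0.118), vehicle 3 (0.202) or high replicate 1 (0.128), 2 (0.069) or 3 (0.244). The calls for NR4A1 and FGA also ended with no low-count filter (0.0666 and 0.13) and that for CYP1A1 on the 6 samples alone (0.066).

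Between the high and the low dose of Citri, 4 genes changed. INSIG1 rose by 0.40 ± 0.05 (adjusted p = 5.2e-05) and CYP1B1 by 0.55 ± 0.10 (0.013), while NR4A1 fell by 0.44 ± 0.07 (0.00335) and FGA by 0.40 ± 0.07 (0.00589). The count was 1 without high replicate 1 or low replicate 3. CYP1B1 was lost without high replicate 1 (adjusted p = 0.152), low replicate 1 (0.17), high replicate 2 (0.245) or low replicate 3 (0.235), NR4A1 without high replicate 1 (0.0567) or low replicate 3 (0.0873), and FGA without high replicate 1 (0.0567), high replicate 3 (0.14) or low replicate 3 (0.0873). Cholesterol genes again shifted upward together, 1 passing over all genes and 5 adjusted over the list alone (camera adjusted p = 2.95e-22). The medium dose changed 3 genes. KLF2, a transcription factor of the Krüppel family, rose by 0.91 ± 0.17 and CMTM8 by 0.68 ± 0.12 (adjusted p = 0.0131 for both). The antisense gene TUBA1B-AS1 (chromosome 12, 49127782 to 49147869), chosen after its values were seen, stood at 819.9 CPM in Citri medium replicate 1, the library set apart above, and at 0.1047 to 0.4568 CPM in vehicle (adjusted p = 0.000501), so that no fold is given. With all libraries 3638 genes had an unadjusted p under 0.05 and DESeq2 called 85. Without medium replicate 1 edgeR called 0, and without medium replicate 2 or 3, which leaves that library with 1 other, 2377 and 2247 genes were. Leaving out vehicle 1 or vehicle 2 gave 1 and leaving out vehicle 3 gave 7. The adjusted p of both KLF2 and CMTM8 was 0.296 without vehicle 1, 0.0827 without vehicle 2 and 1 without medium replicate 1, 0.131 with the length balance as a covariate and 0.683 on the 6 samples alone. At the low dose the only call was AL157400.5, a processed pseudogene on chromosome 10 (89644603 to 89645223), also chosen after its values were seen, with 0.6635 to 1.372 CPM against 0.03691 to 0.1571 in vehicle (adjusted p = 0.00636). That count was 0 without vehicle 1, vehicle 2 or low replicate 3 and 2 without vehicle 3, with 560 genes at an unadjusted p under 0.05 and 2 calls by DESeq2.

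Cimicifugae at the high dose raised the same receptor targets further. CYP1B1 reached 139 ± 4.80 CPM (1.37 ± 0.10, adjusted p = 6.75e-13), CYP1A1 went from 0.848 ± 0.297 to 5.23 ± 0.177 CPM (2.58 ± 0.19, 6.09e-13), and TIPARP, which encodes a repressor of the receptor, rose from 33.4 ± 0.273 to 72.5 ± 1.36 CPM (1.12 ± 0.11, 2.04e-09). HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214), coding for heme oxygenase 1, rose by 0.76 ± 0.09 (5.3e-08). NR4A1 fell from 36.9 ± 1.06 to 15.0 ± 1.14 CPM (-1.295 ± 0.08, 2.42e-16), with its relative NR4A3 (-1.32 ± 0.14, 3.48e-08). The dominant-negative helix-loop-helix gene ID4 (ENSG00000172201, chromosome 6, 19837386 to 19840684) went from 8.88 ± 0.266 to 4.10 ± 0.312 CPM (-1.12 ± 0.13, 8.25e-08), the helix-loop-helix gene ATOH8 fell by 0.82 ± 0.11 (3.04e-06), and the imprinted non-coding RNA H19 (chromosome 11, 1995176 to 2001470) fell to 48.8 ± 3.22 CPM (7.28e-07). NPTX1, which codes for a secreted pentraxin, fell from 362 ± 19.2 to 206 ± 2.67 CPM (-0.81 ± 0.12, 1.49e-05).

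Of 9 aryl hydrocarbon receptor targets, 4 rose with Cimicifugae, as many adjusted over the list alone (camera adjusted p = 5.04e-12). Of 19 TGF-beta and YAP-linked genes 4 fell, 5 adjusted over the list alone (3.23e-08), among them PMEPA1 (-0.46 ± 0.05, 6.69e-09), which encodes an inhibitor of TGF-beta signalling, and ANKRD1 (-0.62 ± 0.10, 5.02e-05). The antisense RNA NKILA, which lies beside PMEPA1 on chromosome 20, fell by 0.88 ± 0.13 (8.4e-06). From the NRF2 list 3 of 24 rose, 4 adjusted over the list alone (0.000109, but adjusted p = 0.174 with an estimated correlation). Cholesterol genes rose in 3 of 24 (6.66e-06) and p53 targets in 3 of 22 (0.00473), with 3 and 4 adjusted over each list alone. These counts were smaller without single libraries. TGF-beta had 2 without vehicle 1 or high replicate 2. NRF2 had 1 without vehicle 1, vehicle 2, high replicate 1 or 3. Cholesterol had 1 without vehicle 1. The p53 list had 0 without vehicle 1 or 2 and 1 without any of the other 4. Altogether 340 genes changed, 188 higher and 152 lower, of which 13 and 6 by at least 1 on the log2 scale. The count was 157 without vehicle 1, 154 without vehicle 2, 220 without vehicle 3, and 177, 162 and 200 without high replicates 1, 2 and 3.

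High against low dose of Cimicifugae gave 232 genes, 108 higher and 124 lower, against 11 on the 6 samples alone, 391 in the shared fit less Citri medium 1 and 748 with the length balance as a covariate. NR4A1 fell from 38.9 ± 4.07 CPM at the low dose (-1.37 ± 0.08, 2.48e-17) and ID4 from 9.60 ± 1.56 CPM (-1.23 ± 0.13, 6.75e-09), H19 fell by 1.01 ± 0.11 and ATOH8 by 1.00 ± 0.11, and CYP1B1 rose by 1.23 ± 0.10 (2.88e-11). The count was 119, 121 and 105 without high replicates 1, 2 and 3, and 94 without low replicate 2. A total of 13 lists passed, of which only the receptor targets, with 4 risen, did so with an estimated correlation too (adjusted p = 1.15e-05). At the medium dose 6 genes changed, among them CYP1B1 (0.72 ± 0.10, 8.58e-05), at 88.7 ± 9.66 CPM, the chemokine gene CXCL5, which fell by 0.41 ± 0.05 (8.14e-06) and NR4A1, which fell by 0.48 ± 0.07 (0.000379). Fitted on the 6 samples alone, CXCL5 and NR4A1 missed the threshold (0.161 and 0.167). The low dose changed 2, the zinc finger gene ZNF444 (0.56 ± 0.11, 0.0401) and the pseudogene AL157400.5 at 0.5848 to 1.176 CPM (0.0401), the latter chosen after its values were seen, against 1949 genes at an unadjusted p under 0.05 and 14 by DESeq2. That count was 0 without vehicle 1, vehicle 2, low replicate 2 or low replicate 3, 5 without vehicle 3 and 4 without low replicate 1, and ZNF444 had an adjusted p of 0.739 without vehicle 1, 0.359 without vehicle 2, 0.765 without low replicate 2, 0.111 without low replicate 3, 0.0553 with a replicate block, 0.0673 with mitochondrial genes removed and 0.582 on the 6 samples alone. AL157400.5 was called at the low dose of both Citri and Cimicifugae, which share a set label, against the same vehicle libraries. For this pseudogene a difference between sets cannot be told apart from an effect of extract.

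Bupleuri at the high dose lowered ID4 to 3.14 ± 0.289 CPM (-1.50 ± 0.13, 2.07e-10), ATOH8 by 1.10 ± 0.11 (1.77e-08), NR4A1 to 19.8 ± 1.07 CPM (5.82e-11) and ID2, another inhibitor of DNA-binding gene, from 153 ± 3.86 to 97.6 ± 3.30 CPM (-0.65 ± 0.10, 0.000143). PTGS2, which codes for cyclooxygenase 2, fell from 20.0 ± 1.19 to 11.1 ± 0.605 CPM (-0.84 ± 0.11, 3.97e-06). GREM1 (ENSG00000166923, chromosome 15, 32717974 to 32745107), which encodes a secreted antagonist of bone morphogenetic proteins, rose from 4.66 ± 0.524 to 8.85 ± 1.16 CPM (0.93 ± 0.12, 5.71e-06). CYP1B1 rose by 0.74 ± 0.10 (1.15e-05) and CYP1A1 by 1.54 ± 0.20 (5.71e-06). The receptor targets rose in 3 of 9, 4 adjusted over the list alone (camera adjusted p = 8.29e-06). NF-kB and inflammatory genes rose in 3 of 18, 5 adjusted over the list alone (9.1e-06), among them RELB (0.57 ± 0.11, 0.00162) and NFKB2 (0.35 ± 0.07, 0.00172), both subunits of the non-canonical arm. For 13 glucocorticoid-induced genes the median was 0.018 but the mean -0.063 and the test downward (0.0235), with 2 fallen over all genes and 4 adjusted over the list alone. Among these PDK4, a kinase gene of fasting metabolism, fell by 0.76 ± 0.11 (1.15e-05). In all 123 genes changed, 78 higher and 45 lower, and the count was 52 without vehicle 1, 63 without vehicle 2, and 55, 77 and 79 without high replicates 1, 2 and 3.

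From the low to the high dose of Bupleuri, 61 genes changed, 22 higher and 39 lower, led by ID4 (-1.52 ± 0.13, 1.1e-10), ATOH8 (-1.16 ± 0.11, 2.79e-09), NR4A1 (1.69e-12, 39.4 ± 1.09 CPM at the low dose) and H19 (-0.85 ± 0.11, 1.87e-06) on the lower side. GREM1 (0.82 ± 0.12, 2.85e-05) and the cadherin gene CDH4 (0.52 ± 0.07, 1.94e-05) rose. The count was 32, 38 and 37 without high replicates 1, 2 and 3, 38 without low replicate 2 and 34 without low replicate 3. At the medium and at the low dose edgeR called 0 genes, with 1755 and 1366 at an unadjusted p under 0.05 and 8 and 2 calls by DESeq2. Leaving out medium replicate 2 gave 1.

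Aconiti raised the 12S mitochondrial ribosomal RNA at every dose. Its gene MT-RNR1 (ENSG00000211459, mitochondrial chromosome, 648 to 1601) stood at 1570 ± 107 CPM in vehicle, 3680 ± 86.5 at the low dose (1.23 ± 0.18, 0.000156), 23563 ± 2152 at the medium dose (3.91 ± 0.20, 3.11e-19) and 40959 ± 4691 at the high dose (2.39e-22), against at most 3140 in any library of the other extracts or vehicle. The 16S gene MT-RNR2, chosen after its values were seen, was more abundant, at 21720 ± 1040 CPM in vehicle, and rose less, to 59100 ± 5670 CPM at the medium (1.44 ± 0.08, 4.77e-17) and 104100 ± 10700 at the high dose (2.26 ± 0.09, 1.68e-24), with no call at the low dose (0.07 ± 0.08, 0.915). Mitochondrially encoded messengers did not follow as a group. Of 13 tested, 3 were higher and 8 lower at the high dose, for example MT-CYB (1.37 ± 0.17, 1.1e-08) and MT-CO3 (-1.22 ± 0.13, 1.96e-10), and the list's camera adjusted p of 0.0178 became an adjusted p = 0.623 with an estimated correlation. Neighbouring mitochondrial genes are processed from shared precursors, so reads near their borders can be counted for either.

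**Figure D2:**
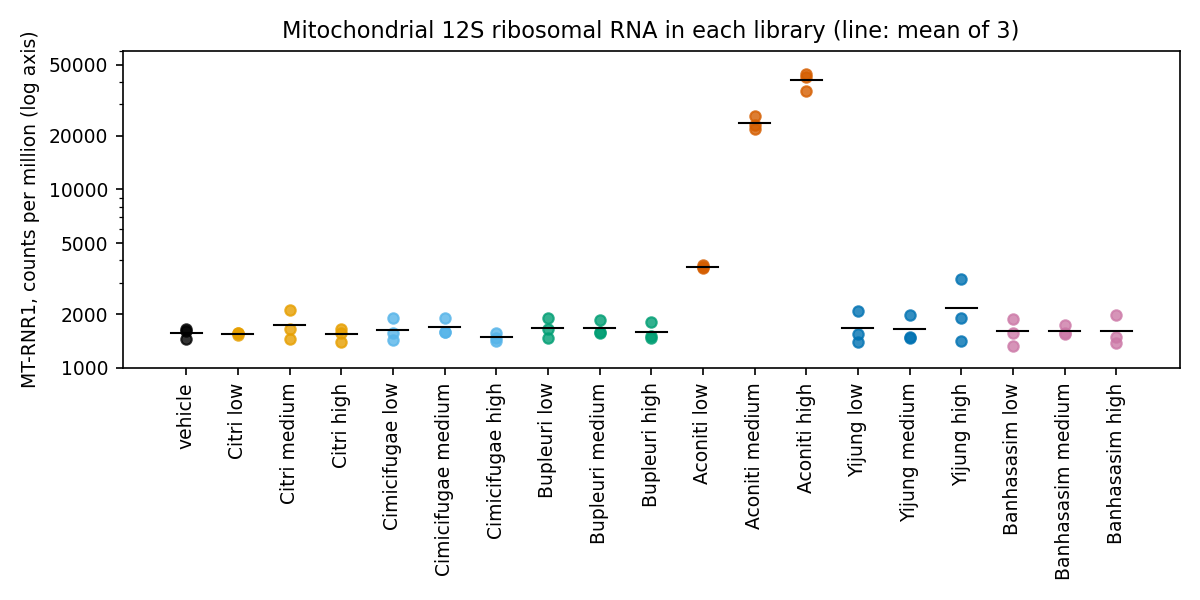
MT-RNR1 in CPM (vertical log axis) in each of 57 libraries (points) by group (horizontal axis), with a line at the mean of 3. The lowest Aconiti medium library lies at 21800, above the highest library outside Aconiti at 3140.

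The high dose of Aconiti raised genes of the ATF4 and amino acid response, 22 of 24 over all genes and 22 adjusted over the list alone (camera adjusted p = 1.76e-37, list median 1.42). The pseudokinase gene TRIB3 (ENSG00000101255, chromosome 20, 362835 to 397559) went from 66.6 ± 3.91 to 414 ± 44.2 CPM (2.64 ± 0.11, 7.68e-23), DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737), which encodes the stress factor CHOP, from 9.54 ± 0.582 to 56.1 ± 4.44 CPM (2.56 ± 0.15, 9.03e-18), and STC2, a stanniocalcin gene, from 28.5 ± 0.362 to 149 ± 20.4 CPM (2.38 ± 0.08, 2.39e-25). Of 16 endoplasmic reticulum chaperones 5 rose and 1 fell (0.00597, adjusted p = 0.0745 with an estimated correlation), HSPA5 going from 635 ± 24.4 to 1036 ± 12.1 CPM. NF-kB and inflammatory genes rose in 15 of 18 over all genes and 16 adjusted over the list alone (9.93e-15). Among them CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716), the gene for the chemokine interleukin 8, went up from 1.03 ± 0.0825 to 7.12 ± 0.924 CPM (2.78 ± 0.21, 1.78e-14). From the p53 list 17 of 22 rose and 1 fell (3.05e-08), including the cell cycle inhibitor CDKN1A (0.89 ± 0.09, 3.98e-11) and the apoptosis gene BBC3 (1.47 ± 0.12, 4.17e-13). Without high replicate 1 no chaperone and 2 p53 targets fell.

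Genes of cell division fell with Aconiti high, 21 of 24 in the mitosis and G2/M list and 22 adjusted over the list alone (7.21e-20), and 17 of 24 in the DNA replication and G1/S list with 19 adjusted over the list alone (9.93e-15). The proliferation marker MKI67 went from 516 ± 63.5 to 195 ± 67.9 CPM (9.1e-05), the ribonucleotide reductase gene RRM2 from 337 ± 0.173 to 191 ± 5.68 CPM (-0.82 ± 0.04, 4.26e-20) and the cyclin gene CCNE2 fell by 1.40 ± 0.13 (8.98e-12). Heat shock proteins fell in 12 of 14 and rose in 1 (1.54e-12), or in 2 without high replicate 1. HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946) went from 360.0 ± 21.8 to 123 ± 13.3 CPM (-1.55 ± 0.10, 1.57e-16), although its reads are shared with the near-identical HSPA1B (-1.32 ± 0.09), and HSPA8 from 2064 ± 26.8 to 1178 ± 39.3 CPM (4.09e-11). Among cholesterol genes 12 fell and 1 rose (0.000233, adjusted p = 0.0745 with an estimated correlation). The fibrinogen gene FGB (ENSG00000171564, chromosome 4, 154562956 to 154571086) fell from 165 ± 6.61 to 80.3 ± 8.63 CPM (5.58e-17). Cytosolic ribosomal proteins rose in 13 of 28 (0.000218), with adjusted p = 0.687 with an estimated correlation, in 4 without vehicle 1, vehicle 2, high replicate 2 or 3, in 7 without vehicle 3 and in 20 without high replicate 1. Their share of counts, 5.315% to 5.759% in vehicle, was 5.632% in high replicate 1, where the long-to-short balance was 3.423, but 6.935% and 6.763% in high replicates 2 and 3, where it was 2.978 and 3.012. Of the 5652 genes, 2942 were higher and 2710 lower, 382 and 196 of them by at least 1 on the log2 scale.

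Between high and low dose of Aconiti 3922 genes changed, 1971 higher and 1951 lower, with MT-RNR1 (3.48 ± 0.19, 1.93e-18), CXCL8, the stress gene NIBAN1 (2.60 ± 0.19) and BEX2 leading the rises and HSPA1A (-1.54 ± 0.10), H19 (-1.50 ± 0.11) and the tubulin-binding protein gene TPPP3 (-1.47 ± 0.22) the falls. Lists that held with an estimated correlation were the ATF4 response (21 of 24 risen, 2.24e-39), NF-kB genes (17 of 18 risen, 1.83e-18), MAPK feedback genes (12 of 16 risen, 3.48e-13), p53 targets (16 risen, 1 fallen), mitosis (21 of 24 fallen, 2.73e-20), DNA replication (18 of 24 fallen) and heat shock proteins (12 of 14 fallen, 1 risen, 4.83e-16). At the medium dose 399 genes changed, 284 higher and 115 lower. The ATF4 list rose there in 20 of 24 (8.29e-67), 22 adjusted over the list alone, and cholesterol genes fell in 12 of 24 (7.67e-17), 14 adjusted over the list alone, while in the mitosis list 3 of 24 fell, 15 adjusted over the list alone (6.41e-12). For cholesterol it was 7 without vehicle 1 or medium replicate 2 and 6 without vehicle 3 or medium replicate 3, and for mitosis 1 without any vehicle library or medium replicate 3. MT-ND5, which codes for a subunit of complex I, went from 2659 ± 196 to 15218 ± 1099 CPM (2.52 ± 0.21, 7.61e-12). The count was 208 without vehicle 1, 225 without vehicle 2, 250 without medium replicate 2 and 226 without medium replicate 3. The low dose raised 12 genes, MT-RNR1, STC2 (0.59 ± 0.08, 0.000107) and CYP1B1 (0.67 ± 0.10, 0.00045) among them, and lowered none. Without vehicle 1, vehicle 3 or low replicate 3 that count was 5, 7 and 6, and CYP1B1 fitted on the 6 samples alone had 0.0749.

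Yijung at the high dose raised immediate-early genes. The transcription factor gene EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) went from 1.55 ± 0.161 to 5.10 ± 0.149 CPM (1.71 ± 0.18, 2.11e-09), FOSL1 (ENSG00000175592, chromosome 11, 65892049 to 65900573), an AP-1 subunit gene, from 28.4 ± 1.54 to 69.9 ± 6.52 CPM (2.33e-17), and the MAPK phosphatase gene DUSP6 rose by 0.93 ± 0.09 (1.18e-10). CXCL8 rose to 6.66 ± 0.921 CPM (2.69 ± 0.21, 3.83e-13) and GREM1 to 17.0 ± 1.97 CPM (1.86 ± 0.12, 8.66e-16). The keratin gene KRT4 (ENSG00000170477, chromosome 12, 52806549 to 52814551) fell from 27.4 ± 1.62 to 7.48 ± 0.941 CPM (-1.87 ± 0.14, 1.91e-13), as did the receptor gene FGFR3 (2.26e-11). FGB fell from 165 ± 6.61 to 74.0 ± 9.12 CPM (1.44e-17) and the collagen gene COL1A1 from 32.2 ± 0.627 to 15.2 ± 1.02 CPM (8.56e-15).

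In the MAPK feedback and immediate-early list 13 of 16 genes rose with Yijung high, 14 adjusted over the list alone (camera adjusted p = 4.21e-29), in the ATF4 list 15 of 24, 17 adjusted over the list alone (2.59e-16), and among NF-kB genes 10 of 18, 10 adjusted over the list alone (4.04e-12). The receptor targets rose in 4 of 9, and adjusted over the list alone 4 rose and 1 fell (0.000604). Ribosome biogenesis genes rose in 3 of 20, 10 adjusted over the list alone (4.57e-05). That count was 1 without high replicate 2, 5 without high replicate 3, 0 with no low-count filter or on the 6 samples alone, 6 by DESeq2 and 10 with the length balance as a covariate. Cholesterol genes fell in 7 of 24, 8 adjusted over the list alone (2.4e-07). Of 14 epithelial keratin and junction genes 2 rose and 3 fell, as many adjusted over the list alone, and the list did not pass (0.494). In total 1224 genes changed, 649 higher and 575 lower, 56 and 80 of them by at least 1 on the log2 scale. The count was 798 without vehicle 1 and 726 without high replicate 2.

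The medium dose of Yijung changed 1355 genes, 693 higher and 662 lower. FOSB (ENSG00000125740, chromosome 19, 45467995 to 45475179), an AP-1 subunit gene, went from 0.855 ± 0.158 to 13.4 ± 2.48 CPM (4.24e-16), EGR1 to 7.91 ± 1.55 CPM (2.34 ± 0.18, 1.93e-13), and COL1A1 to 12.5 ± 0.431 CPM (-1.37 ± 0.08, 8.81e-18). The ATF4 list rose in 18 of 24 (1.85e-37) with 21 adjusted over the list alone, the MAPK list in 12 of 16 (6.04e-30) with 13, and ribosome biogenesis in 10 of 20 (1.02e-08) with 12. A direct comparison of the high with the medium dose, added after the counts were seen, gave 187 genes, 89 higher and 98 lower, against 9 on the 6 samples alone and 719 with the length balance as a covariate, with 106 left without high replicate 1 and 108 without medium replicate 2. High against low dose changed 852 genes, 456 higher and 396 lower, with CXCL8 (2.56 ± 0.20, 8.15e-13), EGR1 (1.82 ± 0.18, 4.16e-10) and GREM1 (1.59 ± 0.12, 6.72e-14) among the rises and KRT4 (-1.93 ± 0.14, 6.72e-14) and the arrestin gene ARRB1 (-1.46 ± 0.12) among the falls. At the low dose 2 genes fell, SFT2D2 (-0.39 ± 0.07, 0.0156) and LINC02977, a non-coding gene on chromosome 9 (112032555 to 112037730) chosen after its values were seen (-0.79 ± 0.14, 0.0156), with 613 genes at an unadjusted p under 0.05 and 5 calls by DESeq2. That count was 0 without vehicle 1, low replicate 1 or low replicate 2 and 1 without vehicle 3, SFT2D2 then having 0.172, 0.146, 0.111 and 0.103.

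Banhasasim at the high dose raised CXCL1, CXCL8 and CXCL5, chemokine genes of the neutrophil-attracting family, which was not tested as a list. CXCL1 (ENSG00000163739, chromosome 4, 73869393 to 73871242) went from 0.955 ± 0.273 to 4.97 ± 0.268 CPM (2.40 ± 0.23, 2.64e-09), CXCL8 from 1.03 ± 0.0825 to 4.72 ± 0.458 CPM (2.19 ± 0.21, 2.64e-09) and CXCL5 (ENSG00000163735, chromosome 4, 73995642 to 73998779) from 82.8 ± 1.24 to 142 ± 5.81 CPM (0.78 ± 0.05, 1.07e-14). The interleukin 1 receptor kinase gene IRAK2 rose by 0.62 ± 0.09 (5.73e-05), CYP1B1 by 0.68 ± 0.10 (0.000151) and GREM1 by 0.72 ± 0.12 (0.00106), while NR4A1 fell to 24.3 ± 1.54 CPM (2.1e-06) and H19 by 0.62 ± 0.11 (0.00106). NF-kB and inflammatory genes rose in 6 of 18, 14 adjusted over the list alone (camera adjusted p = 5.62e-44). The count was 3 without vehicle 1, 12 on the 6 samples alone and 13 with the length balance as a covariate. No single endoplasmic reticulum chaperone of 16 passed over all genes, 3 rose adjusted over the list alone, and the list shifted upward (3.74e-07). Of 19 TGF-beta and YAP-linked genes 1 fell, none without any of the 6 libraries, and 4 adjusted over the list alone (3.54e-05). In all 32 genes changed, 15 higher and 17 lower. The count was 13 without vehicle 1, 18 without vehicle 2, and 17, 18 and 15 without high replicates 1, 2 and 3.

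High against low dose of Banhasasim changed 22 genes, 10 higher and 12 lower, with CXCL5 (0.69 ± 0.05, 7.78e-13), CYP1B1 (0.60 ± 0.10, 0.00157) and IRAK2 (0.59 ± 0.09, 0.000147) higher and NR4A1 (4.84e-07) and H19 (-0.65 ± 0.11, 0.000719) lower. IRAK2 had 0.051 when the 6 samples were fitted alone. NF-kB genes rose in 6 of 18, 10 adjusted over the list alone (5.03e-33). The count was 9, 12 and 13 without high replicates 1, 2 and 3, 10 without low replicate 1 and 12 without low replicate 3. The medium and the low dose gave 0 calls by edgeR, with 467 and 600 genes at an unadjusted p under 0.05 and 3 and 6 calls by DESeq2, and 1 call at either dose without vehicle 3.

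**Figure D3:**
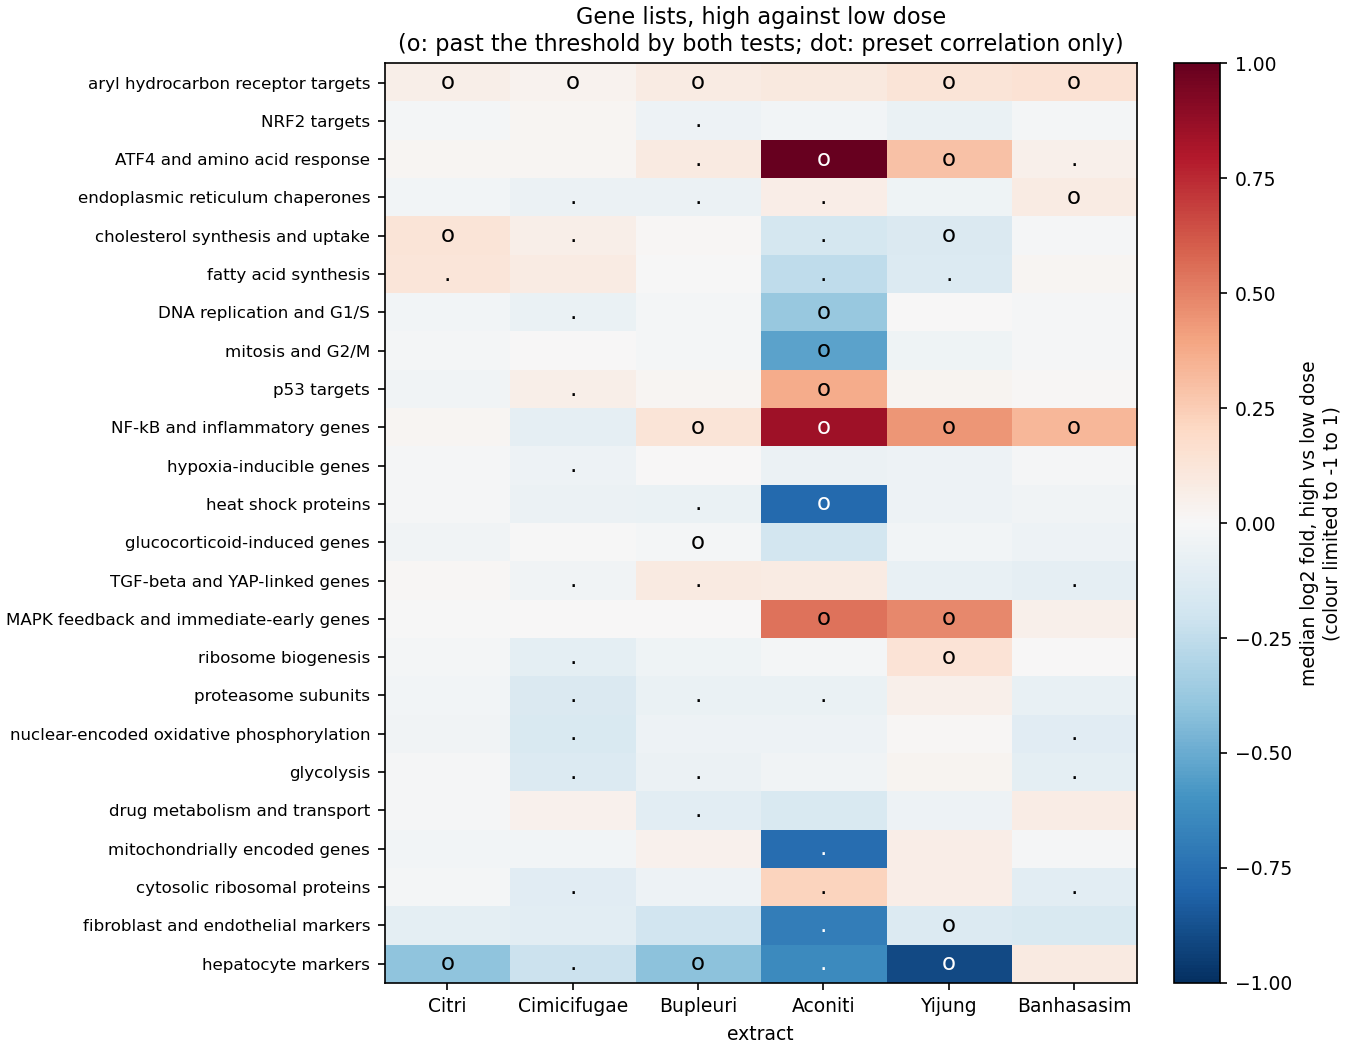
Median log2 fold of gene lists (rows) between the high and the low dose of 6 extracts (columns), 3 libraries per group, with colour limited to -1 to 1. A circle marks lists past the camera threshold with preset and estimated correlation and a dot those with the preset correlation alone, the ATF4 list for example with 21 of 24 genes risen in Aconiti.

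Across all extracts the camera calls that held with an estimated correlation were, of those past the threshold with the preset one, 4 of 12 for Citri high against vehicle, 5 of 11 for Cimicifugae, 3 of 9 for Bupleuri, 8 of 14 for Aconiti, 7 of 9 for Yijung and 4 of 8 for Banhasasim. From low to high dose they were 3 of 4, 1 of 13, 4 of 12, 7 of 15, 8 of 9 and 3 of 8 in that order. Lists for which no loss is given above are among those that held. CYP1B1 was higher at the high than at the low dose in all 6 extracts, by 0.55 in Citri, 1.23 in Cimicifugae, 0.80 in Bupleuri, 0.30 in Aconiti, 0.44 in Yijung and 0.60 in Banhasasim, the Citri call ending without high replicate 1 (0.152), low replicate 1 (0.17), high replicate 2 (0.245) or low replicate 3 (0.235) and the Aconiti call without high replicate 1 (0.0716), high replicate 3 (0.0875) or low replicate 3 (0.155) and on the 6 samples alone (0.12). NQO1, an NRF2 target, passed in none of the high-dose comparisons with vehicle, nor did TXNIP, and CDKN1A passed in Aconiti alone. Whether these differ between extracts is not shown by such calls.

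**Figure D4:**
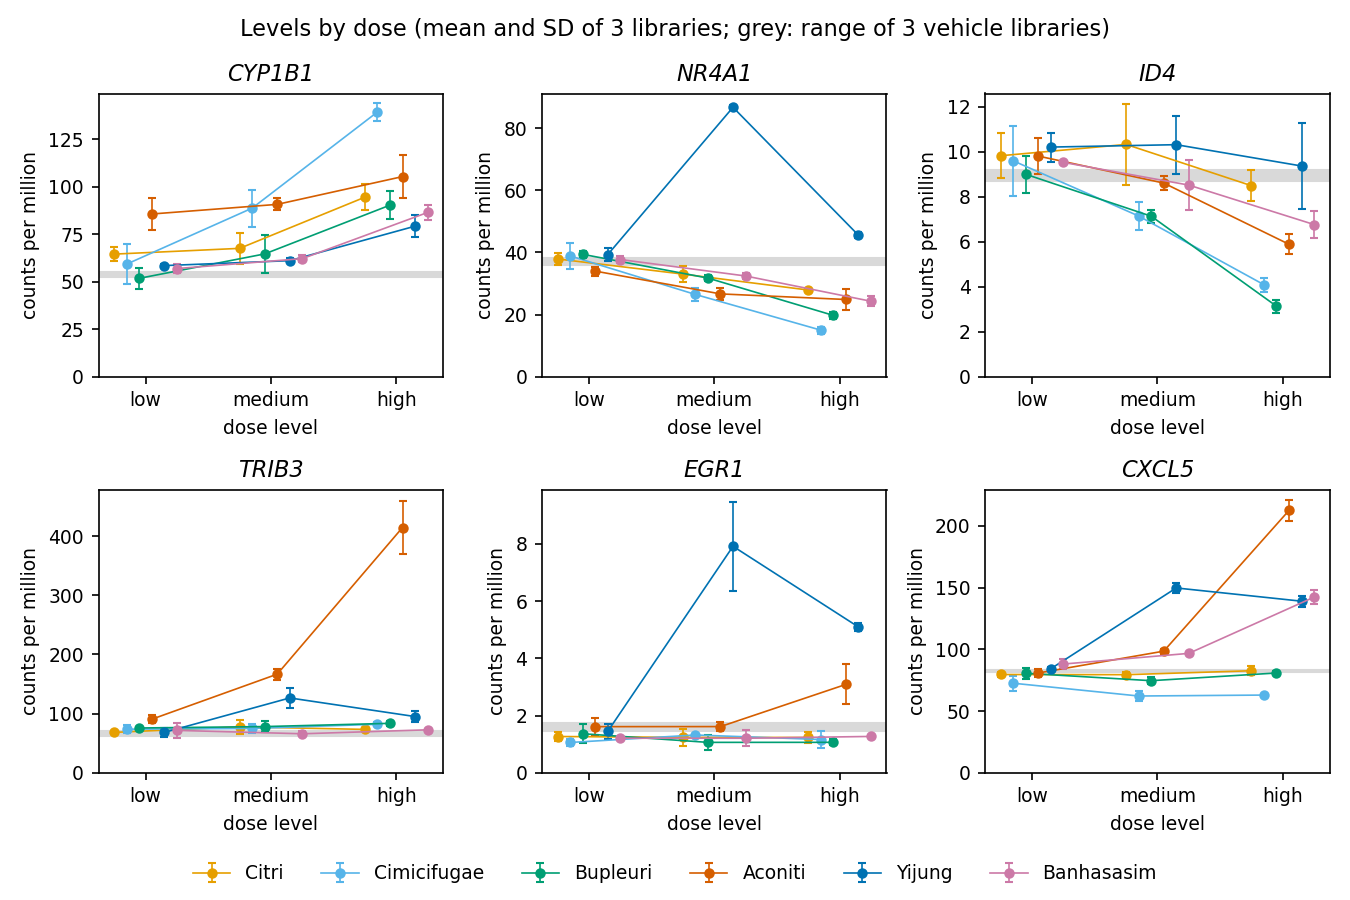
CPM (vertical axes) of 6 genes at the low, medium and high dose (horizontal axes) of 6 extracts, mean and SD of 3 libraries, with the range of the 3 vehicle libraries in grey. NR4A1 falls to 15.0 in Cimicifugae high from 36.9 in vehicle, and CXCL5 reaches 142 in Banhasasim high from 82.8.

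Direct comparison of high doses within a set gave 119 genes between Citri and Cimicifugae, 74 higher in Citri and 45 lower. ID4 was 8.50 ± 0.682 CPM in Citri and 4.10 ± 0.312 in Cimicifugae (1.05 ± 0.13, 6.14e-07), NR4A1 was higher in Citri by 0.89 ± 0.08 (1.09e-10) and ATOH8 by 0.78 ± 0.11 (1.66e-05), and CYP1A1 was lower (-1.46 ± 0.17, 3.78e-07). Receptor targets were lower in Citri in 3 of 9, 4 adjusted over the list alone (8.42e-06), and TGF-beta and YAP-linked genes higher in 3 of 19, 6 adjusted over the list alone (1.21e-10). Leaving out Citri high 1, 2 or 3 gave 68, 62 and 66 genes, and leaving out Cimicifugae high 1, 2 or 3 gave 66, 71 and 68. Between Bupleuri at 500 µg/mL and Aconiti at 360 µg/mL, doses that differ, 3981 genes differed, 2045 higher in Bupleuri and 1936 lower. HSPA1A was higher in Bupleuri, at 351 ± 16.3 CPM (1.51 ± 0.10, 4.28e-16), and MT-RNR1 lower, at 1594 ± 177 CPM (-4.68 ± 0.20, 3.66e-22), with the ATF4 list lower in 22 of 24 (1.92e-45) and the mitosis list higher in 22 of 24 (1.66e-20).

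Yijung and Banhasasim at the high dose differed in 828 genes, 449 higher in Yijung and 379 lower. EGR1 was higher in Yijung (2.00 ± 0.19, 1.51e-10), as were NT5E, coding for the ectonucleotidase CD73, with 72.2 ± 2.17 against 31.3 ± 0.0756 CPM (1.21 ± 0.08, 1.21e-15), and LY6K (2.04 ± 0.29, 1.84e-06). KRT4 (-1.47 ± 0.14, 3.02e-10) and the complement gene C3 (-1.43 ± 0.15, 1.13e-09) were lower. MAPK feedback genes were higher in Yijung in 13 of 16, 14 adjusted over the list alone (3.45e-30), and cholesterol genes lower in 8 of 24, 11 adjusted over the list alone (6.79e-11), whereas NF-kB genes did not pass (0.407). Without Yijung high 2 the count was 467 and without Banhasasim high 2 it was 509. Between low doses of different extracts, the 5 pairs that include Aconiti gave 9 to 17 genes, Cimicifugae against Banhasasim gave 1, which was CXCL5 (-0.28 ± 0.05, 0.0369), and each of the other 9 gave 0 by edgeR, with 291 to 2164 genes at an unadjusted p under 0.05, although DESeq2 called at least 1 gene in each of the 15 pairs.

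Among genes that changed from low to high dose, the medium-dose mean lay between the other means for 4 of 4 in Citri, 224 of 232 in Cimicifugae (96.6%), 61 of 61 in Bupleuri, 3625 of 3922 in Aconiti (92.4%), 588 of 852 in Yijung and 22 of 22 in Banhasasim. Choosing genes by their difference between low and high dose raises this share by itself, and no value for unchanged genes was computed. For Citri it was 45.5% of the genes called on the 6 samples alone and 68.4% of those called with the length balance as a covariate. In Yijung 244 of the others lay beyond the high dose. The median gene had gone 80.1% of the way at the medium dose of Yijung, against 23.0% to 34.5% in the other extracts. Folds between high and low dose, which share no libraries between extracts, were weakly correlated across genes, which are not independent replicates. Pearson's r over all genes was highest for Aconiti and Yijung, 0.179 (jackknife SE 0.111), followed by Bupleuri and Banhasasim, 0.112 (0.058), and Cimicifugae and Bupleuri, 0.102 (0.108). Over genes with at least 10 CPM it was highest for Cimicifugae and Banhasasim, 0.579, followed by Cimicifugae and Bupleuri, 0.572, and Bupleuri and Banhasasim, 0.443, with 0.435 for Citri and Cimicifugae and 0.427 for Aconiti and Yijung. From low to high dose the mean long-to-short balance rose in Citri (3.365 to 3.417), Cimicifugae (3.205 to 3.374), Bupleuri (3.232 to 3.296) and Banhasasim (3.395 to 3.461). It fell in Aconiti (3.293 to 3.138) and Yijung (3.375 to 3.306). Pairs whose balance moved the same way had r of 0.331 to 0.579, and the other pairs -0.125 to 0.045. The correlations were not computed with the balance as a covariate, so its part in them is not separated. Cimicifugae and Bupleuri shared 12 risen and 22 fallen genes where independent lists would share 0.138 and 0.28. Aconiti and Yijung shared 254 and 161, against 52 and 44.7, and 45 genes went opposite ways, against 96.7. SLC2A3, a glucose transporter gene, fell from low to high dose in 5 of the 6 extracts, as did HEXIM1 and CD24, all chosen after their values were seen, and NR4A1 and H19.

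**Figure D5:**
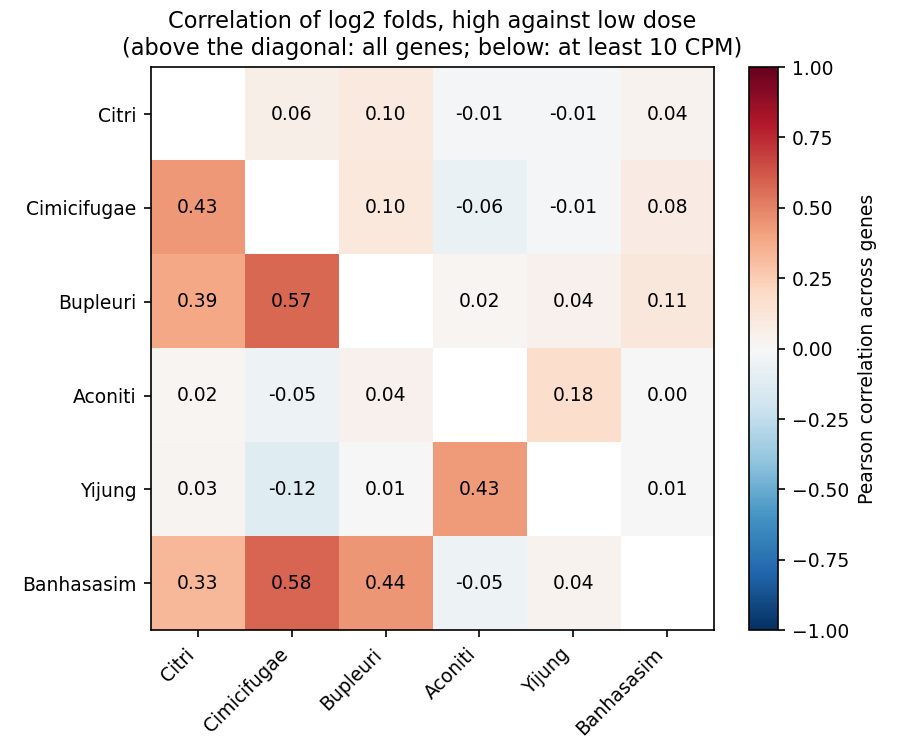
Pearson correlation across genes of log2 folds between the high and the low dose for each pair of 6 extracts (both axes), above the diagonal for all 17269 genes and below it for those with at least 10 CPM. Below the diagonal Cimicifugae reaches 0.579 with Banhasasim and 0.572 with Bupleuri, and above it the highest value is 0.179 for Aconiti and Yijung.

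Bojungikgi had 1 library per dose, so its differences have no replicate check and no test. CYP1B1 stood at 95.8 CPM at the high dose, 67.4 at the medium and 59.4 at the low dose, a log2 difference of 0.68 from low to high, the largest rise of 9478 genes with at least 10 CPM, whose differences had an SD of 0.107. TIPARP followed the pseudogene RPL4P4 with 0.58. The largest falls, RGPD5 (-1.09) and MT-ATP8 (-1.06), are a multicopy gene and a gene that overlaps its neighbour, and H19 went from 106 to 62.1 CPM (-0.76). Against 10000 random lists matched on expression, the medians of receptor targets, ATF4 and NF-kB genes lay at percentile 100 and that of proteasome subunits at 0.01, a description of these libraries. Across genes its difference correlated with the folds of Cimicifugae at 0.365, Bupleuri 0.333, Banhasasim 0.307, Citri 0.294, Aconiti 0.124 and Yijung 0.12. Over genes with at least 1 CPM the values were 0.208, 0.154, 0.185, 0.177, 0.105 and 0.107, so that the order depends on this limit. The long-to-short balance was 3.389 in the low-dose and 3.512 in the high-dose library, and the Bojungikgi values are not corrected for it.

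Markers of other cell types were low or belonged to the line. Of immune markers 3 genes were testable, at 8.35 CPM summed over vehicle, of which 1, CD68, chosen after its values were seen, rose with Yijung high (camera adjusted p of the list 0.385) and none in Aconiti high. Fibroblast and endothelial markers summed to 39.4 CPM in 5 genes, of which 1, COL1A1, fell with Yijung high (0.0296, adjusted p = 0.0512 with an estimated correlation) and 2 with Aconiti high (0.0979). Hepatocyte markers, at 316 CPM in 5 genes, fell in 2 with Yijung high (6.8e-07) and in 1 between low and high dose of Citri (1.73e-09), that gene being FGA, lost without high replicate 1 (0.0567), high replicate 3 (0.14) or low replicate 3 (0.0873). With Aconiti high 2 of these fell and 1 rose, none without any of the 6 libraries (0.0216, adjusted p = 0.224 with an estimated correlation).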

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

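The tests of a general gain of mitochondrial RNA, of counts taken by it and of the length balance in other splits were chosen only after the result was seen, and the fits with the length balance as a covariate and without mitochondrial genes were added after seeing the data.

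Responses from low to high dose differed between extracts by a test of the difference itself (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted). The number of genes that differed was 1705 between Citri and Aconiti, 2185 between Cimicifugae and Aconiti, 1718 between Bupleuri and Aconiti, 1611 between Aconiti and Yijung and 1880 between Aconiti and Banhasasim. With Yijung it was 290 for Citri, 571 for Cimicifugae, 309 for Bupleuri and 226 for Banhasasim. It was 10 between Citri and Cimicifugae, 3 between Citri and Bupleuri, 3 between Citri and Banhasasim, 14 between Cimicifugae and Banhasasim and 10 between Bupleuri and Banhasasim, and 1 between Cimicifugae and Bupleuri. The genes that differed between Citri and Bupleuri were ID4 (-0.21 and -1.52, adjusted p of the difference 8.35e-05), ATOH8 (-0.22 and -1.16, 0.00287) and NR4A1 (-0.44 and -0.996, 0.023). Between Citri and Banhasasim they were the chemokine genes CXCL5 (0.05 and 0.69, 5.64e-07), CXCL8 (-0.38 and 1.92, 3.53e-05) and CXCL1 (-0.01 and 1.95, 0.00489), and between Cimicifugae and Bupleuri IGFBP3, which codes for a binding protein of insulin-like growth factors (-0.39 and 0.14, 5.62e-05). IGFBP3, SMOX and the examples of opposite change were chosen after their values were seen. These counts were not recomputed without single libraries.

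Some genes went opposite ways. PTGS2 fell with Cimicifugae (-0.58) and rose with Aconiti (0.49, adjusted p of the difference 7.27e-07). The spermine oxidase gene SMOX went from -0.44 with Cimicifugae to 1.40 with Aconiti (5.43e-15). INSIG1 rose with Citri (0.40) and fell with Yijung (-0.30, 1.77e-08). Opposite changes were seen in 27 genes for Cimicifugae and Aconiti, where independent lists would give 26.4, in 28 for Cimicifugae and Yijung (5.75) and in 45 for Aconiti and Yijung (96.7), fewer than that number. It was 5 for Bupleuri and Yijung (1.53), 4 for Bupleuri and Aconiti (6.94), 1 each for Citri and Yijung (0.0987), Cimicifugae and Banhasasim (0.147) and Aconiti and Banhasasim (2.5), and 0 for the other pairs. Genes are not independent, so these numbers were not tested.

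Lists past the threshold in opposite directions also differed. For cholesterol synthesis and uptake, higher with Citri and Cimicifugae and lower with Aconiti and Yijung, the adjusted p of the difference was 8.32e-10 for Citri and Aconiti, 9.95e-19 for Citri and Yijung, 8.1e-05 for Cimicifugae and Aconiti and 4.67e-07 for Cimicifugae and Yijung. TGF-beta and YAP-linked genes were higher with Bupleuri and lower with Cimicifugae (2.34e-11) and Banhasasim (9.22e-10). Endoplasmic reticulum chaperones were lower with Cimicifugae than with Aconiti (2.26e-05) and Banhasasim (1.93e-07), and lower with Bupleuri than with Aconiti (7.15e-06) and Banhasasim (1.6e-09). Ribosome biogenesis was lower with Cimicifugae than with Yijung (5.12e-07). The differences in fatty acid synthesis between Citri and Aconiti (0.00151) and Citri and Yijung (0.00026) had adjusted p = 0.296 and 0.202 with an estimated correlation. Those in cytosolic ribosomal proteins between Cimicifugae and Aconiti (0.000416) and Aconiti and Banhasasim (0.000683) had 0.628 and 0.679. The other differences held. Of the lists within an extract, cholesterol in Citri (1.22e-05) and Yijung (0.0128), ribosome biogenesis in Yijung (0.0239) and endoplasmic reticulum chaperones in Banhasasim (0.0237) held with an estimated correlation. Those of cholesterol in Cimicifugae (0.331) and Aconiti (0.136), of TGF-beta and YAP-linked genes in Cimicifugae (0.158), Bupleuri (0.0711) and Banhasasim (0.121), of chaperones in Cimicifugae (0.174), Bupleuri (0.0601) and Aconiti (0.0529), and of ribosome biogenesis in Cimicifugae (0.0733) were lost, so there the direction within an extract is less sure than the difference. For fatty acid synthesis and cytosolic ribosomal proteins all directions within an extract (0.355 to 0.882) were lost as well as the differences.

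Aconiti at the high dose changed 5652 genes. Had mitochondrial transcripts merely taken counts from the rest, nuclear genes would all shift by -0.15 log2 (from count shares). Of 5639 nuclear genes changed, 3723 lay farther than that from the nuclear median by over 2 standard errors. Scaling removes such a shift and these genes were picked as changed, so 3723 cannot decide. With mitochondrial genes removed before scaling, the count moved by at most 1.5 times. With the length balance as a covariate it was 6591. These values argue against lost counts or the balance as the whole cause. A toxic dose and an action of its own constituents stay open, since Aconiti alone was dosed at its IC20.

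The 12S mitochondrial ribosomal RNA rose with the dose of Aconiti, and the 16S RNA rose less and not at the low dose. The lowest Aconiti medium library had 6.94 times the MT-RNR1 level of the highest library outside Aconiti (21800 against 3140 CPM), which argues against poly(A) selection or RNA breakdown that varies between libraries regardless of treatment. The median log2 fold of 13 mitochondrial messengers at the high dose was -0.77 (range -1.22 to 1.37), which argues against a general gain of mitochondrial RNA. An effect of the extract on polyadenylation, processing or turnover of ribosomal RNA may be at work, as may a change in how such RNA enters the library that is tied to the treatment, and the counts cannot separate these.

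Yijung changed as many genes at the medium as at the high dose, 1355 and 1224. With the length balance as a covariate the counts were 3291 and 2705, and the lowest count on leaving out 1 medium library was 994, which argue against the balance and against 1 deviating medium library as the cause. An exchange of dose labels, a saturated response and a biphasic one stay open for the response as a whole. The direct comparison of high with medium dose, with 187 genes but 9 on the 6 samples alone, does not decide between them. NR4A1 stood at 37.5 to 41.53 CPM at the low, 85.94 to 87.45 at the medium and 45.09 to 46.56 at the high dose. CYP1B1 stood at 57.69 to 58.95, 59.59 to 62.29 and 72.59 to 82.91. Neither labelling puts both in dose order, but 2 genes picked after their values were seen do not settle it.

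Other splits of the 6 libraries of a comparison into 3 and 3 make 10 splits, too few for a share under 0.05, and were fitted on those 6 libraries alone. For high dose against vehicle 1 split, the real one, reached the real count, which was 52 in Citri (highest other 8), 1932 in Cimicifugae (4), 1024 in Bupleuri (0), 4275 in Aconiti (0), 622 in Yijung (1) and 144 in Banhasasim (8). For the medium dose 10 splits reached it in Citri (0, highest other 0) and Bupleuri (0, 1), 2 in Cimicifugae (4, 4), and 1 each in Aconiti (1132, 0), Yijung (892, 0) and Banhasasim (17, 6). At the low dose it was 10 in Bupleuri (0, 1473) and Banhasasim (0, 5), 2 in Citri (23, 346) and Aconiti (2, 2) and 1 in Cimicifugae (3, 1) and Yijung (5, 4). Between low and high dose it was 2 in Bupleuri (41, 1246) and 1 in Citri (33, 15), Cimicifugae (11, 0), Aconiti (1501, 1072), Yijung (344, 9) and Banhasasim (7, 1). Between high doses it was 1 for Citri and Cimicifugae (1078, 2), Bupleuri and Aconiti (2470, 0) and Yijung and Banhasasim (354, 1), and 2 for Yijung high and medium (9, 196). Another split called more genes than the real one in 6 comparisons. In 2 of them, Bupleuri medium (1 against 0) and Banhasasim low (5 against 0), the long-to-short balances of the sides overlapped, in Banhasasim low with 3.188 to 3.523 against 3.362 to 3.5. The other 4 splits, with far more calls, set Citri low 1 and 3 with vehicle 3 (346), Bupleuri low 1 with vehicle 1 and 2 (1473), Bupleuri high 1 with Bupleuri low 2 and 3 (1246) and Yijung high 1 and 2 with medium 1 (196) against the rest. In each of the 4 the balances of the sides, scaled over 57 libraries, did not overlap, as holds for 1 of 10 splits, with 3.323 to 3.362 against 3.438 to 3.523, 3.418 to 3.523 against 3.123 to 3.362, 3.123 to 3.21 against 3.311 to 3.418 and 3.087 to 3.39 against 3.442 to 3.537. The same holds for the split with 1072 in Aconiti (3.355 to 3.474 against 2.979 to 3.051).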

How the results depend on the processing

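The covariate, robust, mitochondrial-gene and less-1-library fits, and the comparison of Yijung high with medium dose, were chosen only after the data had been seen. No called gene or list changed direction under the alternatives run. In Bojungikgi, which has no test, 1 list did. RLE size factors and a robust spread moved none of 28 counts of changed genes by more than 1.5 times. DESeq2 moved 16 of 28, all upward, the covariate 26 (25 upward), the fit without a filter 21 (8 upward), only the 6 samples 21 (10 upward), the shared fit less Citri medium replicate 1 moved 13 (12 upward), and leaving out 1 library 80 of 168 (71 downward). Of 325 called named values, 4 were lost by DESeq2, 5 with the covariate, 31 without a filter, 37 with only the 6 samples, 6 with the replicate block and 2 each with RLE, robust and less-1-library fits, 280 of 1950 on leaving out a library and 4 of 307 with mitochondrial genes removed. Of 185 counts of risen or fallen members in lists past the threshold, 40 moved by more than 1.5 times without a filter, 76 with only the 6 samples, 73 with the covariate, 29 less 1 library, 16 by DESeq2, 15 with mitochondrial genes removed, 6 with RLE, 4 with the block and 1 with a robust spread, and 252 of 1110 on leaving out a library (235 downward). A left-out library and a fit of 6 samples have fewer samples by construction, and otherwise the cause was not tested. Genes near 1 CPM limit what depth can show.

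On simulated data with genes drawn independently, DESeq2 on 6 samples made 48 false calls, against 7 for edgeR on those 6 and 14 in the shared edgeR fit of 57. DESeq2 on all 57 libraries was not simulated, so how many of its calls here are false is not known. By DESeq2 the counts were 22 for Aconiti low against vehicle, 38 for Banhasasim high against low, 55, 3 and 6 for Banhasasim high, medium and low against vehicle, 95 for Bupleuri high against low, 186, 8 and 2 for Bupleuri high, medium and low, 17 and 14 for Cimicifugae medium and low, 16, 85 and 2 for Citri high, medium and low, 7 for Citri high against low and 5 for Yijung low. Of 15 pairs of low-dose groups, 6 had a changed gene, 15 by DESeq2 and 10 with the covariate.

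With the length balance as a covariate, counts against vehicle were 1050 and 28 for Aconiti medium and low, 179, 6 and 26 for Banhasasim high, medium and low, 645 and 17 for Bupleuri high and medium, 1384, 75 and 9 for Cimicifugae, 41, 1 and 5 for Citri and 2705, 3291 and 14 for Yijung. From low to high dose they were 6117 for Aconiti, 90 for Banhasasim, 273 for Bupleuri, 748 for Cimicifugae, 19 for Citri and 1942 for Yijung. Between high doses they were 6090 for Bupleuri and Aconiti, 480 for Citri and Cimicifugae and 1799 for Yijung and Banhasasim, and 719 for Yijung high against medium.

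Without a filter, counts against vehicle were 188 for Aconiti medium, 18, 2 and 3 for Banhasasim high, medium and low, 60, 2 and 1 for Bupleuri, 141 and 5 for Cimicifugae high and low, 5, 120 and 2 for Citri and 820, 875 and 5 for Yijung. From low to high dose they were 9 for Banhasasim, 33 for Bupleuri, 111 for Cimicifugae and 562 for Yijung. Between high doses they were 63 for Citri and Cimicifugae and 488 for Yijung and Banhasasim, and 74 for Yijung high against medium.

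With only the 6 samples compared, counts against vehicle were 1132 and 2 for Aconiti medium and low, 144 and 17 for Banhasasim high and medium, 1024 for Bupleuri high, 1932, 4 and 3 for Cimicifugae, 52, 0 and 23 for Citri and 622, 892 and 5 for Yijung. From low to high dose they were 1501 for Aconiti, 7 for Banhasasim, 41 for Bupleuri, 11 for Cimicifugae, 33 for Citri and 344 for Yijung. Between high doses they were 2470, 1078 and 354 for Bupleuri and Aconiti, Citri and Cimicifugae, and Yijung and Banhasasim, and 9 for Yijung high against medium. In the shared fit less Citri medium replicate 1 they were 664 for Aconiti medium, 34 and 55 for Banhasasim high against low and vehicle, 116, 211 and 4 for Bupleuri high against low, high and medium, 391, 545, 15 and 5 for Cimicifugae high against low, high, medium and low, 187 for Citri and Cimicifugae, 0 for Citri medium and 282 for Yijung high against medium. With mitochondrially encoded genes removed Cimicifugae low had 0.

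The replicate number as a block across sets brought Cimicifugae low from 2 to 0 and moved no other count by over 1.5 times. In 0 of 27 comparisons did every pair of equal number correlate above 0.1. In 1, Banhasasim high against vehicle, each library correlated best with its own number. MT-RNR1 peaked in replicate 1 of each Yijung and Banhasasim group. Pairing within sets stays open.

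Leaving out 1 library at a time gave ranges of counts. Against vehicle at the high, medium and low dose they were 2 to 5, 0 to 2377 and 0 to 2 for Citri, 154 to 220, 5 to 8 and 0 to 5 for Cimicifugae, 52 to 86, 0 to 1 and 0 to 0 for Bupleuri, 3970 to 6522, 208 to 313 and 5 to 9 for Aconiti, 726 to 1406, 953 to 1340 and 0 to 2 for Yijung, and 13 to 25, 0 to 1 and 0 to 1 for Banhasasim. From low to high dose they were 1 to 4, 94 to 219, 32 to 54, 2949 to 4439, 570 to 840 and 9 to 15 in the same order of extracts. Between high doses they were 62 to 71, 3041 to 4412 and 467 to 1043 for the sets of Citri, Bupleuri and Yijung, and 106 to 161 for Yijung high against medium.

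With an estimated inter-gene correlation, lists past the threshold for high dose against vehicle numbered 4 for Citri, 5 for Cimicifugae, 3 for Bupleuri, 8 for Aconiti and 4 for Banhasasim, for high against low dose 1 for Cimicifugae, 4 for Bupleuri, 7 for Aconiti and 3 for Banhasasim, and between high doses 4 for Citri and Cimicifugae and 6 for Yijung and Banhasasim. Over 561 list results 90 calls were lost that way, the block gained 2 and RLE gained 8.

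The percentage of changed genes with the medium dose between was, with the covariate, 68.4 for Citri, 87.0 for Cimicifugae, 94.5 for Bupleuri, 85.8 for Aconiti, 63.7 for Yijung and 93.3 for Banhasasim. With only the 6 samples it was 45.5 for Citri, 100 for Cimicifugae, 97.6 for Bupleuri, 95.6 for Aconiti and 73.5 for Yijung. Less Citri medium replicate 1 it was 98.3 for Bupleuri and 67.1 for Yijung, by DESeq2 98.9 and 67.4, and without a filter 71.4 for Yijung. On leaving out a library the lowest value for Banhasasim was 93.3 and the highest 100.

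Spearman correlations of dose responses were 0.22 for Citri and Cimicifugae, 0.197 for Citri and Bupleuri, 0.162 for Citri and Banhasasim, 0.339 for Cimicifugae and Bupleuri, 0.274 for Cimicifugae and Banhasasim and 0.225 for Bupleuri and Banhasasim. Over genes with at least 10 CPM Pearson's r was 0.435, 0.385, 0.331, 0.572, 0.579 and 0.443 for these pairs and 0.427 for Aconiti and Yijung. For Bojungikgi over genes with at least 1 CPM it was 0.177 with Citri, 0.208 with Cimicifugae, 0.154 with Bupleuri and 0.185 with Banhasasim. There the median of epithelial keratins and junctions went from percentile 99.86 to 2.2, with more list members included.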

Other observations

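All 7 further gene lists used here were chosen only after the data were seen. Apart from the list of BMP targets, their p-values therefore describe the listed genes in these same data and are no independent support. The tests of BMP targets and of Bojungikgi were written down before their results.

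With Yijung high against vehicle, genes listed for cell adhesion shifted upward and listed liver-type genes that A549 cells express shifted downward. Of 15 integrin, laminin and urokinase-system genes 9 rose, 10 adjusted over the list alone (camera adjusted p = 3.8e-13, adjusted p = 0.00312 with an estimated correlation), among them the urokinase gene PLAU (0.78 ± 0.06, 1.91e-13) and the hyaluronan receptor gene CD44 (0.71 ± 0.06, 1.25e-11). Of 16 hepatic transcription factor and fibrinogen-linked genes 9 fell, 10 adjusted over the list alone (1.2e-13, adjusted p = 1.72e-05 with an estimated correlation), with HNF4A, a master regulator of liver genes (6.49e-14), and the fibrinogen gene FGG (-0.93 ± 0.09, 4.36e-11). Between low and high dose 7 and 9 of these passed in the same directions (6.99e-14 and 1.33e-19). The hepatic list was lower from low to high dose also with Aconiti, 8 fallen (1.06e-05, adjusted p = 0.0122 with an estimated correlation), Bupleuri, 3 fallen (1.03e-08 and 0.000662), and Citri, 1 fallen (3.28e-06 and 0.00573). With Cimicifugae, not passing (0.297), 2 rose, or 2 rose and 5 fell adjusted over the list alone. With Banhasasim 0 moved, or 1 rose and 3 fell (0.05 and 0.418). The 1 in Citri was 0 without high replicate 1 or 3 or low replicate 3. Against vehicle 9 fell and 2 rose with Aconiti high (0.000258 and 0.0363), the 2 being 1 without vehicle 1 or high replicate 2, the Bupleuri call was lost with an estimated correlation (0.0146 and 0.227), and the list did not pass with Citri (0.262), Cimicifugae (0.491) or Banhasasim (0.466). The adhesion list also shifted upward with Aconiti, 6 risen against vehicle (0.00645) and 6 risen and 1 fallen from low to high dose (0.000732), with Banhasasim against vehicle (0.0317) and with Bupleuri from low to high dose, 1 risen (0.0158), and downward with Cimicifugae against vehicle (0.0153), but with an estimated correlation these had 0.292, 0.167, 0.847, 0.459 and 0.484. The 1 fallen in Aconiti was 0 without high replicate 1 or 3 or any low library, and the 1 risen in Bupleuri was 0 without any high library or low replicate 2 or 3.

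Aconiti at the high dose raised 11 of 20 cytosolic aminoacyl-tRNA synthetase genes and lowered 2 (camera adjusted p = 4.87e-08, adjusted p = 0.0764 with an estimated correlation), with SARS1 (1.11 ± 0.09, 5.44e-13) and AARS1 (0.94 ± 0.07, 5.48e-15) among those risen. Of 11 amino acid transporters 6 rose and 1 fell (6e-05, adjusted p = 0.0363 with an estimated correlation), among them the glycine transporter gene SLC6A9 (3.6e-20) and SLC1A4 (1.22 ± 0.07, 1.3e-18). The 2 lowered synthetase genes were 1 without any of the 6 libraries, and the 1 fallen transporter was 2 without high replicate 1 and 0 without high replicate 2 or 3. Of 36 mitochondrial ribosomal protein genes 9 rose and 1 fell, and the list did not pass (0.0813). Genes of mitochondrial RNA synthesis and processing went both ways, 3 up and 6 down of 16 (0.218). With Yijung high the synthetases (1.78e-06), transporters (0.006), mitochondrial ribosomal proteins (0.00134) and mitochondrial RNA genes (9e-04) shifted upward too, with 0.116, 0.122, 0.532 and 0.0433 with an estimated correlation.

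ID4, NR4A1 and ATOH8 fell with Cimicifugae and Bupleuri from low to high dose. Lower BMP signalling was a hypothesis for this, and 8 other BMP targets would then have moved lower in both. Their camera p was 0.0343 in Cimicifugae, in the lower direction with 1 fallen, where the adjusted p was 0.08 and 0.138 with an estimated correlation, and 0.8 in Bupleuri, in the higher direction. After adjustment neither passed, and the hypothesis stays undecided.

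Bojungikgi-tang as commonly prescribed holds Citri, Cimicifugae and Bupleuri among its herbs. Its difference between high and low dose correlated across genes with the folds of these 3 more than with those of Aconiti and Banhasasim, by 0.115 on average over genes with at least 10 CPM, where 0.1 was set in advance for shared herbs, but by only 0.035 over genes with at least 1 CPM. Banhasasim at 0.307 also exceeded Citri at 0.294, 1 library per dose was measured and genes are not independent replicates. Yijung (0.12) was left out. Herbs of Yijung and Banhasasim were not checked, so the contrast does not single out shared herbs. The long-to-short balance of Bojungikgi rose from 3.389 at the low to 3.512 at the high dose. The group means rose too in Citri, Cimicifugae, Bupleuri and Banhasasim, but fell in Aconiti and Yijung. Whether shared herbs or this balance account for the excess stays undecided.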
